A study of Mus musculus with 10 samples.

How the data were processed

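Total RNA from ileal crypts of mice was sequenced single-end. The labels describe 10 libraries in 3 groups: 3 libraries of control mice (Ctrl), 2 of mice with Stat5 deleted from the intestinal epithelium (KO) and 5 of mice described as overexpressing Stat5 (OE). The OE label names an allele, icS5, that it does not spell out, and no control of that allele's line is analysed here. All mice are labelled male, C57Bl6 and 12 weeks old. Per the labels' protocols, crypts were shaken off the tissue in buffer with 10 mM EDTA at 37 C for 30 min. Each library is labelled as a sample of its group, but nothing says that the libraries came from separate animals, so p-values measure the spread between these samples, and part of that spread can be technical.

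The deposited values are TPM, a share of all transcripts, for 28987 Ensembl gene IDs in each library, per the file headers in 9 of the 10 libraries. The header of Ctrl 1 gives no unit, and its unit was taken from the other libraries and from its values. TopHat, Cufflinks and the mouse build mm10 are named in the submitters' processing notes, without versions. Which tool gave the TPM and which annotation was used are not given in the sources used here. TPM keep no read numbers, so the depth of each library is unknown, and no counting interval can be given. Deposited TPM summed to between 979539 and 994373 per library. Symbols, classes and coordinates of the genes were taken by ID from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. A symbol was found for 27458 IDs and none for 1529, of which 246 were tested. There are 43 sets of IDs with identical values in all libraries, 92 IDs in all, and how reads were split between near-identical copies is not given. Alpha-defensins, Lyz1 and Lyz2, haemoglobin genes, Reg3 genes and pseudogenes are uncertain for that reason.

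TPM were divided by median-ratio factors computed over the 11146 genes above 0 in every library, and are called scaled TPM. Genes with a deposited TPM of at least 1 in at least 2 libraries were kept, which left 13056. Tests were run in limma 3.58.1 (R 4.3.3) on log2(scaled TPM + 1) with an intensity trend, on all 10 libraries with 3 group means and no further term. The 3 contrasts were KO against Ctrl, OE against Ctrl and OE against KO. Fold changes are on that log2 scale, which understates the change of genes near the pseudocount of 1. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Group values are means ± SD of scaled TPM, and intervals are 95% intervals of the limma fit.

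Of 37 gene lists for crypt cell types, pathways, stress programs and other cells of the gut wall, 34 had at least 3 measured genes. They were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists within a comparison. Camera with an estimated correlation and fry were the alternatives. For single values, exact two-sided permutation tests were used. The lists, the limma and camera tests, the groups and the rule for naming genes were fixed before the data were examined. The plan did not name the exact permutation tests of single genes. For OE against KO it foresaw no named list members, so those named here go beyond it. The rule took Stat5a and Stat5b in every library, the genes of the study's title, the 3 genes with the smallest p in each direction where none was called (libraries not overlapping, a mean of at least 5 scaled TPM in the higher group, predicted genes and small RNAs left out), and up to 4 members of each list described, by mean level where none was called. Which lists have members named was chosen after the list results were seen. Genes past the threshold when adjusted over their list alone were also named after their values were seen.

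The fit was tested on simulated data with the spreads of these genes. In 5 runs, 6.4% of the genes changed 2-fold were recovered for KO against Ctrl, 16.8% for OE against Ctrl and 9.2% for OE against KO. Of the genes changed 8-fold, 82%, 89.2% and 87.6% were recovered. The changed genes were drawn only from those with a mean of at least 3 on the log2 scale. The shares thus do not cover genes as low as Stat5a, Stat5b and Gfi1. In these runs 26, 23 and 19 unchanged genes were called. In simulated data without changes, 0 genes and 0 lists were called. The simulated genes varied independently of each other, so the 0 lists do not test the preset correlation on lists whose members vary together. In the real data the estimated correlation within a list reached 0.895, for the mitochondrial respiratory chain. Alternatives were values as deposited, quantile normalization, pseudocounts of 0.1 and 5, no filter or a stricter one of 5 TPM, only the groups compared, robust and weighted limma fits, a replicate block, a false discovery rate of 0.1, a 1.5-fold minimum, and leaving out each library in turn. Chosen after seeing the data were protein-coding genes only, a Y-linked covariate, leaving out 3 libraries low in Y-linked transcripts, leaving out Ctrl 2 with the library labelled OE 1, and an exact permutation test of list means. Count-based tests planned for read counts were not run, since the values are not counts. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.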

Results

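The study sequenced RNA from ileal crypts, the pits of the small intestine that hold stem cells, dividing progenitors and Paneth cells, in mice without epithelial Stat5, in controls and in mice labelled as overexpressing it. STAT5A and STAT5B are transcription factors activated by cytokine and growth hormone receptors. The title of the study concerns Paneth cell function and the genes Wnt3a, Tcf7l2 (also called Tcf4), Sox9 and Gfi1. There were 3 Ctrl, 2 KO and 5 OE libraries. The values are TPM, so the depth of each library is unknown.

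Stat5a (ENSMUSG00000004043, chromosome 11, 100859351 to 100885169) and Stat5b (ENSMUSG00000020919, chromosome 11, 100780731 to 100850724) lie next to each other in mm10. Stat5a was at 1.73 ± 0.785 scaled TPM in Ctrl (SD, n = 3), 0.487 ± 0.213 in KO (SD, n = 2) and 2.57 ± 0.763 in OE (SD, n = 5). Stat5b was at 1.48 ± 0.444 in Ctrl, 0.456 ± 0.0369 in KO and 3.58 ± 1.61 in OE, with the same numbers of libraries. By library, Stat5a was at 1.51, 2.60 and 1.07 in Ctrl 1, 2 and 3, and at 0.637 and 0.336 in KO 1 and 2. It was at 2.10, 3.55, 2.81 and 2.81 in OE 2, 3, 4 and 5. Stat5b was at 1.72, 1.76 and 0.970 in Ctrl 1, 2 and 3, at 0.482 and 0.430 in KO 1 and 2, and at 3.50, 4.71, 5.53 and 2.65 in OE 2, 3, 4 and 5. The library labelled OE 1 had 1.56 scaled TPM of Stat5a and 1.49 of Stat5b, within the range of the Ctrl libraries, and each direction given for the OE group includes it. Every OE library lay above both KO libraries for both genes, and every KO library lay below every Ctrl library in scaled values. In values as deposited, KO 1 lay above Ctrl 2, at 0.771 against 0.765 TPM for Stat5a and 0.583 against 0.517 for Stat5b, so that separation depends on the scaling of Ctrl 2. The exact two-sided permutation p was 0.0476 for each gene in OE against KO, the smallest that 21 splits can give, and 0.2 for each in KO against Ctrl, where 0.1 is the smallest possible. In OE against Ctrl the exact permutation p was 0.161 for Stat5a and 0.0893 for Stat5b. After adjustment over the 18 tests of this family, the exact permutation p was 0.429 for both genes in OE against KO. No test of this family could pass 0.05 after adjustment, whatever the values, so this result was fixed by the design. The smallest possible permutation p before adjustment is 0.1 for KO against Ctrl, 0.0179 for OE against Ctrl and 0.0476 for OE against KO.

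**Figure D1:**
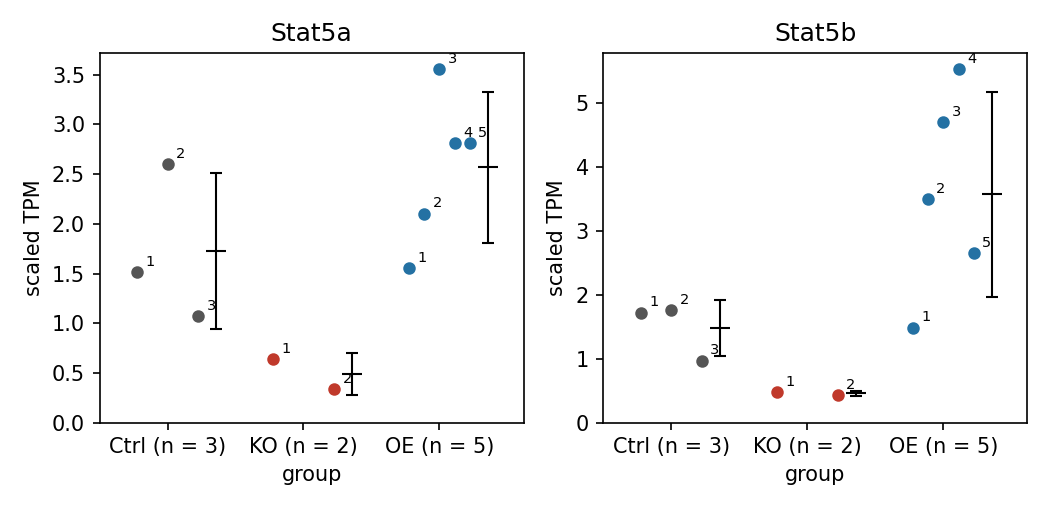
Scaled TPM of Stat5a and Stat5b (vertical axes) by group, with 1 point per library, numbered by replicate, and the mean ± SD beside the points. In these scaled values both KO libraries lie below every other library, which for KO 1 and Ctrl 2 is not so in values as deposited, and the library labelled OE 1 lies within the range of the 3 Ctrl libraries for both genes.

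Ctrl 2 stood apart from the other libraries. Transcripts encoded in mitochondria took 83.7% of its TPM against 43.3% to 56.97% elsewhere, and mt-Atp8 alone took 55.2% against 16.9% to 38.2%. It had 8263 genes at 1 TPM or more, where the others had 11050 to 11932, and its median-ratio factor was 0.295 against 0.831 to 1.31. In scaled values its mean level of enterocyte genes was the highest of all libraries, at 8.76 on the log2 scale against 5.45 to 7.61, and its mean of Paneth cell genes was the lowest, at 2.27 against 4.20 to 6.41. The enterocyte rank depends on the scaling: as deposited, Fabp2 was at 942 TPM in Ctrl 2 and 2183 in the library labelled OE 1, and Anpep at 684 and 1663. The summed TPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 3.45 in Ctrl 3, 0.250 in OE 3 and 0.140 in OE 4, and between 32.3 and 131 in the other libraries, although every mouse is labelled male. Xist was not analysed here.

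**Figure D2:**
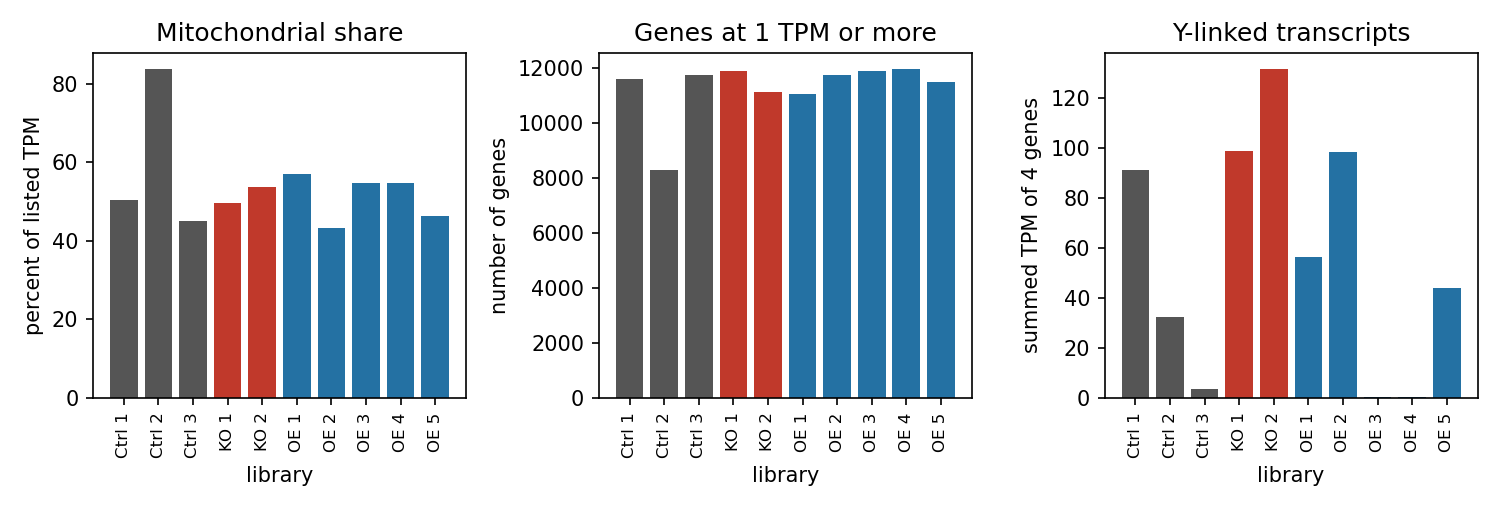
Share of TPM from mitochondrial genes, number of genes at 1 TPM or more and summed TPM of 4 Y-linked genes, with 1 bar per library coloured by group. Ctrl 2 has the highest mitochondrial share (83.7%) and the fewest genes (8263), and Ctrl 3, OE 3 and OE 4 have almost no Y-linked TPM.

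Loss of Stat5 was examined by KO against Ctrl. At the preset correlation, genes of fibroblasts and of macrophages and dendritic cells passed as higher in KO, and genes of enterocytes and of the interferon response as lower, with adjusted p = 0.749, 0.634, 0.749 and 0.749 with an estimated correlation. The fibroblast median of 1.27 was 0.53 without KO 1, the enterocyte median of -0.87 was -0.17 without Ctrl 2, and no single gene passed the threshold. Lyz2, a lysozyme of macrophages and uncertain as a close paralog of Lyz1, was at 137 ± 47.6 scaled TPM in KO (SD, n = 2) and 7.80 ± 4.68 in Ctrl (SD, n = 3), a log2 difference of 4.13 (95% interval 1.95 to 6.31). Cpt2, a mitochondrial enzyme of fatty acid oxidation, was at 7.84 ± 2.22 in KO and 31.1 ± 10.2 in Ctrl, a log2 difference of -1.83 (-2.70 to -0.96). Both had an adjusted p of 0.943 in limma. Lyz2 was not high in KO alone. Every OE library also lay above every Ctrl library for it, at 11.6 to 193 against 2.39 to 10.7 scaled TPM. The library labelled OE 1, at 193, lay above both KO libraries (171 and 104).

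Other genes with the smallest p were Pdk3, a kinase that inhibits pyruvate dehydrogenase, at 33.1 ± 4.65 in KO and 14.9 ± 3.15 in Ctrl, and the pseudogene Rps2-ps13, at 303 ± 38.0 and 0.0292 ± 0.0506. Inpp1, an inositol phosphatase, was at 0.874 ± 0.916 and 6.26 ± 3.11, and Slc28a1, a nucleoside transporter, at 1.21 ± 1.43 and 31.4 ± 33.1. In scaled values every OE library also lay above every Ctrl library for Pdk3 (18.2 to 26.2 in OE) and below every Ctrl library for Inpp1 (1.00 to 3.18 in OE). As deposited, Pdk3 was at 15.1 TPM in the library labelled OE 1 and 21.6 in Ctrl 1. Inpp1 was at 3.76 in OE 4 and 2.81 in Ctrl 2, so neither separation holds there. These genes were picked for lying apart from the same Ctrl libraries, so OE lying on the same side as KO is no separate support. Values of Rps2-ps13 and Slc28a1 in OE are not given here. Among the genes of the title, Sox9 (chromosome 11, 112782224 to 112787760), a transcription factor needed for Paneth cells, was at 14.6 ± 1.95 in KO and 11.7 ± 7.99 in Ctrl, with a log2 difference of 0.56 (-0.71 to 1.83), which was -0.12 without Ctrl 2 and 1.02 without Ctrl 3. Gfi1 (chromosome 5, 107716657 to 107726036), a transcription factor of secretory cells, was at 2.09 ± 0.235 and 1.71 ± 1.48, with a log2 difference of 0.40 (-1.04 to 1.84), which was -0.22 without Ctrl 2, 0.71 without Ctrl 1 and 0.69 without Ctrl 3. Tcf7l2 (chromosome 19, 55741820 to 55933654), a transcription factor of the Wnt pathway, was at 13.3 ± 5.07 and 15.6 ± 1.63. Its log2 difference of -0.26 (-0.95 to 0.43) was 0.11 without KO 1, -0.63 without KO 2 and 0.21 in values as deposited, where the median of all genes was 0.38 and not the 0.038 of scaled values. Wnt3a was listed at 0 in all 10 libraries. Wnt3, made by Paneth cells, was under the filter, at 0.211 ± 0.0823 in KO and 0.177 ± 0.164 in Ctrl.

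Of the 34 gene lists, 14 passed camera at the preset correlation, 7 higher and 7 lower in KO, and 0 passed with an estimated correlation. All 10 measured fibroblast genes had positive values, with a median log2 difference of 1.27 (adjusted p = 0.000169, and adjusted p = 0.749 with an estimated correlation), and the median was 0.53 without KO 1, when the list did not pass, and 1.95 without KO 2. Dcn, a matrix proteoglycan, was at 8.12 ± 6.35 in KO and 1.93 ± 1.45 in Ctrl, Sparc at 11.6 ± 10.1 and 2.19 ± 0.700, Vim at 10.96 ± 6.76 and 6.50 ± 5.59, and Col1a1, a collagen, at 7.93 ± 8.29 and 5.38 ± 5.87. Of 14 genes of macrophages and dendritic cells, 13 were positive, with a median log2 difference of 0.85 (adjusted p = 1.5e-06, and adjusted p = 0.634 with an estimated correlation), and the median was 0.44 without KO 1, when the list did not pass, and 1.55 without KO 2. Beside Lyz2, Cd14 was at 7.53 ± 3.45 and 4.66 ± 1.34, Itgam at 7.34 ± 2.10 and 4.72 ± 3.18, and Ctss at 42.9 ± 17.0 and 45.7 ± 18.5. Of 25 enterocyte genes, 21 were negative, with a median log2 difference of -0.87 (adjusted p = 0.000424, and adjusted p = 0.749 with an estimated correlation). The median was -0.17 without Ctrl 2 and -0.68 without KO 1, neither past the threshold, and -1.55 without Ctrl 3. Anpep, a brush border peptidase, was at 623 ± 55.6 in KO and 1306 ± 894 in Ctrl, the fatty acid binding gene Fabp2 at 321 ± 142 and 1437 ± 1574, Apoa1 at 337 ± 120.5 and 1381 ± 1627, and Fabp6, which binds bile acids, at 423 ± 254 and 420.1 ± 353. Of 32 interferon response genes, 25 were negative, with a median log2 difference of -0.43 (adjusted p = 0.00114, and adjusted p = 0.749 with an estimated correlation). The median was -0.17 without Ctrl 3 and -0.50 without KO 1, neither past the threshold, and -0.85 without Ctrl 1. Its most abundant members were Psmb10, at 49.6 ± 9.51 and 42.5 ± 5.29, Irf1, at 40.5 ± 7.42 and 45.7 ± 12.8, Psmb8, at 24.6 ± 11.4 and 32.1 ± 12.9, and Tap2, at 24.3 ± 19.9 and 31.6 ± 13.7.

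Of 25 genes of endoplasmic reticulum stress, 20 were negative in KO against Ctrl, with a median log2 difference of -0.46 (adjusted p = 0.00297, and adjusted p = 0.749 with an estimated correlation). The median was -0.18 without Ctrl 3 and -0.13 without KO 1, neither past the threshold. The chaperone Calr was at 223 ± 7.31 in KO and 375 ± 170.3 in Ctrl, Hsp90b1 at 282 ± 25.1 and 416 ± 171, Canx at 349 ± 115 and 366 ± 187, and Pdia3 at 274 ± 144 and 248 ± 56.97. Of 22 alpha-defensins, antimicrobial peptides of Paneth cells with near-identical copies, 20 were positive, with a median log2 difference of 0.96 (adjusted p = 0.0121, and adjusted p = 0.749 with an estimated correlation). The median was -0.35 without Ctrl 2 and 0.47 without KO 2, neither past the threshold, 1.86 without Ctrl 1 and 1.48 without Ctrl 3. Defa24 was at 1404 ± 558 and 1294 ± 1063, Defa30 at 1009.7 ± 284 and 805 ± 708, Defa31 at 799 ± 372 and 932 ± 733, and Defa17 at 789.6 ± 103 and 901 ± 758. Of 13 other Paneth cell products (paneth), 8 were positive, with a median log2 difference of 0.20 (adjusted p = 0.794, and adjusted p = 0.988 with an estimated correlation), and the list did not pass. It passed as lower without Ctrl 2 (median -0.40, adjusted p = 0.0322) and as higher without Ctrl 3 (0.98, adjusted p = 0.0407), and the median was -0.086 without KO 1. Ribosomal proteins (median 0.56), cell cycle genes (0.41), reserve stem cell genes (0.45) and epithelial antimicrobial genes (0.34) also passed as higher at the preset correlation. They had adjusted p of 0.749, 0.749, 0.634 and 0.749 with an estimated correlation. Genes of T cells (median -0.81), tuft cells (-0.42), JAK-STAT components (-0.27) and the mitochondrial respiratory chain (-0.96) passed as lower. The JAK-STAT list holds Stat5a and Stat5b themselves and was not tested without them, and its median was 0.18 in values as deposited. The 4 lists had adjusted p of 0.749, 0.749, 0.634 and 0.749 with an estimated correlation. When the library in brackets was left out, calls were lost for ribosomal proteins at a median of 0.28 (KO 1) and cell cycle (proliferation) genes at -0.12 (Ctrl 2) and -0.045 (KO 2). They were lost for reserve stem cell genes at 0.56 (Ctrl 1), 0.24 (Ctrl 2), 0.41 (KO 1) and 0.33 (KO 2) and for antimicrobial genes at 0.40 (Ctrl 1) and 0.13 (KO 1). T cells (t_cell) lost their call at -0.55 (Ctrl 3) and -0.38 (KO 1), and tuft cells at 0.27 (Ctrl 3) and 0.37 (KO 2). It was lost for JAK-STAT components (jak_stat) at -0.046 (Ctrl 2) and -0.35 (KO 1) and the respiratory chain (oxphos_mito) at -0.084 (Ctrl 2). Other medians that moved over 1.5-fold were 0.33 (Ctrl 2) for ribosomal proteins, 0.70 (Ctrl 1) and 0.82 (KO 1) for the cell cycle and 0.65 (Ctrl 3), 0.56 (KO 2), 0.16 (labelled OE 1) and 0.16 (OE 2) for antimicrobial genes. They were -1.22 (Ctrl 1) and -0.51 (Ctrl 2) for T cells and -0.85 (Ctrl 2) and -1.17 (KO 1) for tuft cells. Over all genes tested, 0 list members were called, and adjusted over the list alone there were 2, Lyz2 and the chemokine Cxcl5. Cxcl5, named after its values were seen, was at 4.07 ± 0.0947 in KO and listed at 0 in all 3 Ctrl libraries.

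In limma, 0 of 13056 genes were higher and 0 lower in KO than in Ctrl, with 452 at an unadjusted p under 0.05, where chance alone gives 652.8, and robust limma and library weights also called 0. Of the 14 lists, 4 kept their call and direction without KO 1, which leaves 1 KO library, 8 without Ctrl 2, 10 without Ctrl 3, 10 without KO 2 and 12 without Ctrl 1.

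Stat5 overexpression was examined by OE against Ctrl. At the preset correlation, genes of Paneth cells, alpha-defensins, the cell cycle and B cells passed as higher in OE (each with adjusted p = 0.652 with an estimated correlation). Genes of enterocytes and of the mitochondrial respiratory chain passed as lower (adjusted p = 0.738 and 0.652 with an estimated correlation). Without Ctrl 2 the medians of these 2 lower lists were 0.11 and 0.14, the Paneth cell median was 0.12 and that of the cell cycle (proliferation) 0.083, and no single gene passed the threshold with all libraries. Defa31, uncertain because of its near-identical copies, was at 2547 ± 1723 scaled TPM in OE (SD, n = 5) and 932 ± 733 in Ctrl (SD, n = 3), a log2 difference of 1.98 (95% interval 0.0065 to 3.95), which was 0.66 without Ctrl 2. Ube2c, a ubiquitin-conjugating enzyme of mitosis, was at 38.6 ± 8.05 and 21.1 ± 6.99, a log2 difference of 0.86 (0.24 to 1.49). Both had an adjusted p of 0.755 in limma.

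The genes with the smallest p were Stx5a, a syntaxin of Golgi transport, at 5.53 ± 4.01 in OE and 0.252 ± 0.437 in Ctrl, Mrps12, a mitochondrial ribosomal protein, at 24.3 ± 7.79 and 9.34 ± 1.37, and Pmf1, a kinetochore protein, at 5.95 ± 1.20 and 2.21 ± 0.837. On the lower side were the kinase Dyrk1a, at 19.6 ± 5.58 and 44.0 ± 7.16, Coq8a, which serves coenzyme Q synthesis, at 14.7 ± 6.29 and 60.2 ± 31.6, and Decr2, a peroxisomal enzyme, at 13.4 ± 2.08 and 29.1 ± 2.01. Both KO libraries also lay above every Ctrl library for Mrps12 (16.3 and 13.4). In scaled values they lay below every Ctrl library for Dyrk1a (32.3 and 24.9), Coq8a (16.2 and 20.7) and Decr2 (23.7 and 9.65). As deposited, both KO libraries lay above Ctrl 2 for each of these, which was at 15.4, 7.59 and 9.17 TPM. Every OE library also lay above Ctrl 2 for Coq8a as deposited, at 10.2 to 28.3 TPM. These genes were picked for lying apart from the same Ctrl libraries, so KO lying on the same side as OE is no separate support. Values of Stx5a and Pmf1 in KO are not given here. Sox9 was at 13.2 ± 3.36 in OE and 11.7 ± 7.99 in Ctrl, with a log2 difference of 0.40 (-0.62 to 1.41), and Gfi1 at 2.41 ± 1.44 and 1.71 ± 1.48, with a log2 difference of 0.42 (-0.73 to 1.57). Without Ctrl 2 these differences were -0.29 for Sox9 and -0.21 for Gfi1, without Ctrl 1 0.61 and 0.72, and without Ctrl 3 0.85 and 0.70. For Gfi1 it was 0.70 without OE 2 and 0.23 without OE 4. Tcf7l2 was at 14.6 ± 3.07 and 15.6 ± 1.63, with a log2 difference of -0.11 (-0.66 to 0.44). For the gene Tcf7l2 OE against Ctrl gave -0.19 without the library labelled OE 1 and -0.021 without OE 4. It was 0.35 in values as deposited, where the median of all genes was 0.36 and not the 0.021 of scaled values. Wnt3 was at 0.270 ± 0.0595 and 0.177 ± 0.164.

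Of the 34 lists, 14 passed camera at the preset correlation, 12 higher and 2 lower in OE, and 0 passed with an estimated correlation. All 13 Paneth cell genes had positive differences, with a median log2 difference of 0.89 (adjusted p = 0.00438, and adjusted p = 0.652 with an estimated correlation), and the median was 0.12 without Ctrl 2, when the list did not pass, and 1.80 without Ctrl 3. Lyz1, uncertain as a close paralog of Lyz2, was at 1556 ± 1257 in OE and 950.3 ± 1102 in Ctrl, Itln1 at 1226 ± 729.7 and 645 ± 476, Ang4 at 525 ± 487 and 314 ± 397, and Mptx2 at 266 ± 171 and 173 ± 243. Of 22 alpha-defensins, 21 were positive, with a median log2 difference of 1.68 (adjusted p = 2.15e-07, and adjusted p = 0.652 with an estimated correlation), and the median was 0.44 without Ctrl 2. Beside Defa31, Defa24 was at 2798 ± 1614 and 1294 ± 1063, Defa30 at 2058 ± 1172 and 805 ± 708, and Defa17 at 2024 ± 1401 and 901 ± 758. Of 30 cell cycle genes, 29 were positive, with a median log2 difference of 0.64 (adjusted p = 1.3e-07, and adjusted p = 0.652 with an estimated correlation), and the median was 0.083 without Ctrl 2, when the list (proliferation) did not pass. Beside Ube2c, Top2a was at 97.2 ± 16.8 and 66.8 ± 53.9, Stmn1 at 64.3 ± 10.4 and 39.9 ± 23.4, and Cdk1 at 43.6 ± 8.14 and 27.7 ± 7.74. Of 11 B and plasma cell genes, 10 were positive, with a median log2 difference of 1.39 (adjusted p = 4.24e-06, and adjusted p = 0.652 with an estimated correlation). Jchain, of the joining chain of antibodies, was at 43.9 ± 39.9 and 15.1 ± 10.5, Ms4a1 at 9.68 ± 13.4 and 0.559 ± 0.948, and Pou2af1 at 4.87 ± 6.31 and 0.295 ± 0.339. OE 4 was far above the other OE libraries, at 33.5 against 0.622 to 5.59 for Ms4a1, 16.0 against 0.463 to 3.14 for Pou2af1 and 112 against 15.8 to 43.4 for Jchain, and the median of the list was 1.09 without it (b_plasma). Of 17 genes known as STAT5 targets in other tissues, 10 were positive, with a median log2 difference of 0.038 (adjusted p = 0.777, and adjusted p = 0.862 with an estimated correlation), and the list did not pass. Its median was 0.18 without Ctrl 2 and -0.021 without Ctrl 1 (list stat5_targets). Among them, Socs2, a feedback inhibitor of cytokine signalling, was at 65.5 ± 10.7 in OE and 91.0 ± 50.4 in Ctrl, Mcl1 at 86.4 ± 13.1 and 88.5 ± 15.6, Cdkn1a at 58.8 ± 30.2 and 58.9 ± 21.1, and Ccnd1 at 36.5 ± 10.5 and 21.8 ± 15.6. Ccnd1 was at 35.9, 4.98 and 24.6 in Ctrl 1, 2 and 3, so its gap rests largely on Ctrl 2. In KO against Ctrl 12 of the 17 targets were negative (median -0.21, mean 0.0065, adjusted p = 0.712 in camera, and 0.818 with an estimated correlation). In OE against KO 11 were positive (median 0.11, adjusted p = 0.564 in camera, and 0.786 with an estimated correlation).

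Ribosomal proteins (median 0.51), T cells (0.64), macrophages and dendritic cells (0.48) and MHC class II genes (0.44) also passed as higher in OE than in Ctrl at the preset correlation. So did fibroblasts (0.56), mast cells (0.55), red blood cell genes (1.31) and the list of dissociation and immediate early genes (0.32). The adjusted p was 0.729 for fibroblasts and 0.652 for each of the others with an estimated correlation. Enterocyte genes (median -0.64) and the mitochondrial respiratory chain (-0.73) passed as lower, with adjusted p of 0.738 and 0.652 with an estimated correlation. When the library in brackets was left out, calls were lost for T cells at a median of 0.39 (Ctrl 1), MHC class II genes at 0.41 (Ctrl 1), 0.41 (Ctrl 3) and 0.33 (labelled OE 1), and fibroblasts at 0.43 (Ctrl 1), 0.25 (labelled OE 1) and 0.40 (OE 3). Calls were lost for mast cells at 0.60 (Ctrl 1), 0.50 (Ctrl 2), 1.22 (OE 4) and 0.83 (OE 5) and red blood cell genes at 1.80 (Ctrl 1), 1.38 (Ctrl 3), 1.10 (labelled OE 1), 0.97 (OE 3) and 1.21 (OE 5). They were also lost for dissociation and immediate early genes at 0.11 (Ctrl 1), 0.51 (Ctrl 3), 0.26 (labelled OE 1), 0.30 (OE 4) and 0.25 (OE 5). Enterocytes lost their call at 0.11 (Ctrl 2), -0.62 (OE 2) and -0.35 (OE 4) and the respiratory chain (oxphos_mito) at 0.14 (Ctrl 2). Other medians that moved over 1.5-fold were 0.84 (Ctrl 3) and 1.05 (OE 2) for mast cells, -1.34 (Ctrl 3) for enterocytes and -1.23 (Ctrl 1) and -1.16 (Ctrl 3) for the respiratory chain. Over all genes tested, 0 list members were called, and adjusted over the list alone there were 7. Among these were the B cell genes Cd79a, Cd79b, Ms4a1, Cd22 and Pou2af1, and Axin1 of the Wnt list, at 9.15 ± 2.33 in OE and 2.86 ± 1.63 in Ctrl, named after their values were seen. In KO against Ctrl, 8 of 11 B and plasma cell genes were also positive (median 0.63). That list did not pass (adjusted p = 0.0992 in camera, and 0.749 with an estimated correlation). Both KO libraries lay above every Ctrl library for Ms4a1 (6.67 and 5.21) and Cd22 (1.93 and 0.851). KO 2 lay below Ctrl 1 for Cd79a and Cd79b.

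In limma, 0 of 13056 genes were higher and 0 lower in OE than in Ctrl, with 797 at an unadjusted p under 0.05 against 652.8 by chance, and robust limma and library weights also called 0. Of the 14 lists, 8 kept their call and direction without Ctrl 1, 9 without Ctrl 2 and 10 without the library labelled OE 1, and 11 to 14 without any other library.

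**Figure D3:**
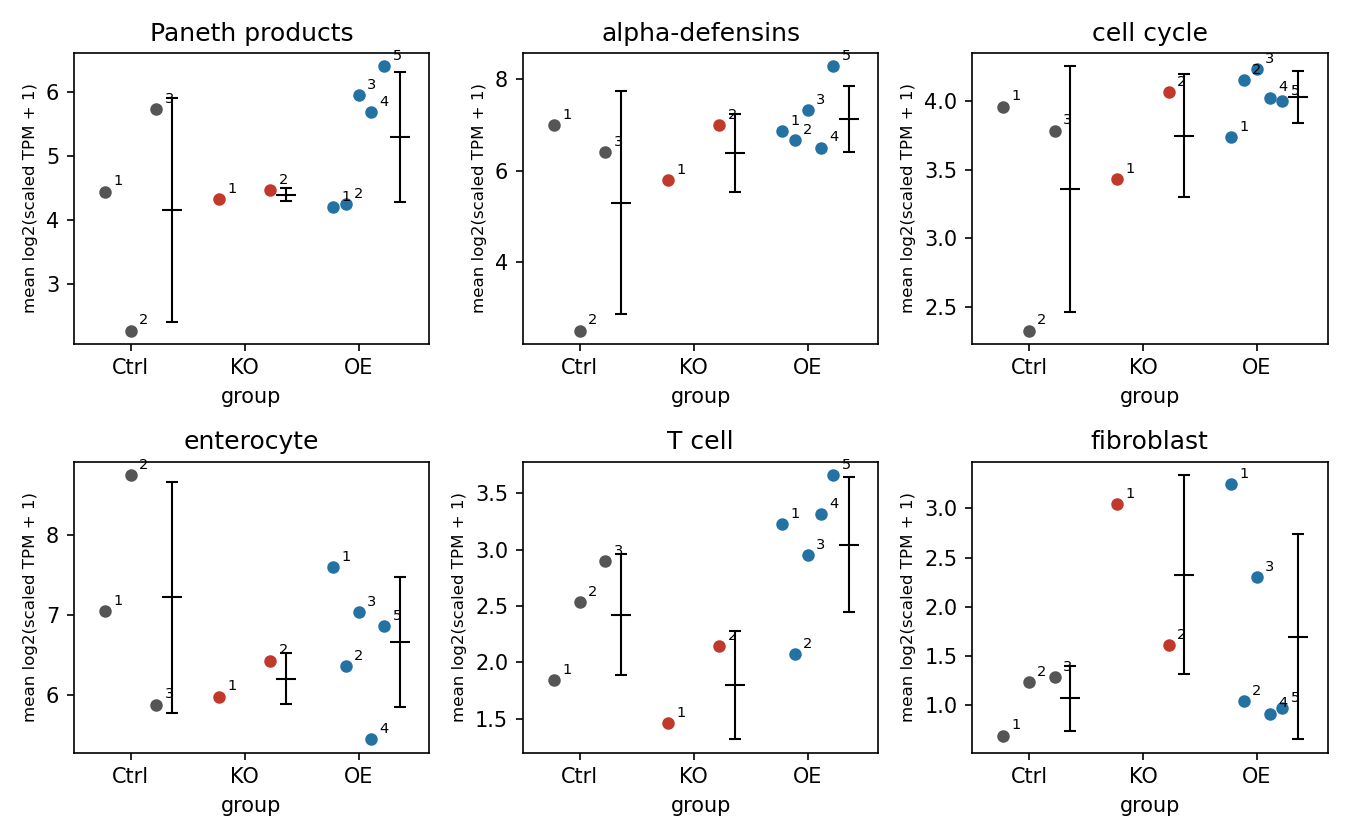
Mean log2(scaled TPM + 1) of 6 gene lists (vertical axes) by group, with 1 point per library, numbered by replicate, and the mean ± SD beside the points. In these scaled values Ctrl 2 has the lowest Paneth cell mean (2.27) and the highest enterocyte mean (8.76), and the T cell means of 4 of the 5 OE libraries lie above both KO libraries.

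OE against KO compared the opposite Stat5 manipulations directly. At the preset correlation, genes of T cells and intraepithelial lymphocytes passed as higher in OE than in KO. So did tuft cell genes, Paneth cell genes and the list of dissociation and immediate early genes, while fibroblast genes passed as lower. These lists had adjusted p = 0.541, 0.786, 0.786, 0.541 and 0.786 with an estimated correlation, and the tuft cell median was -0.18 without KO 2 and the fibroblast median 0.026 without KO 1. Gzma, a granzyme of cytotoxic lymphocytes, was at 121 ± 70.5 scaled TPM in OE (SD, n = 5) and 19.1 ± 13.3 in KO (SD, n = 2), a log2 difference of 2.55 (95% interval 1.10 to 4.01). The lymphocyte kinase Lck was at 25.4 ± 11.7 and 5.69 ± 0.0171, a log2 difference of 1.85 (0.81 to 2.88). The adjusted p of both over all genes was 1 in limma.

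The genes with the smallest p were the pseudogene Rpl30-ps9, at 37.4 ± 17.9 in OE and 0.394 ± 0.557 in KO, Sharpin, a part of a ubiquitin ligase, at 19.7 ± 2.29 and 9.43 ± 1.47, and Slc25a10, a mitochondrial carrier, at 41.7 ± 8.31 and 19.5 ± 4.90. Ctnnbl1 was at 13.3 ± 2.97 and 29.1 ± 1.98, the kinesin Kif24 at 3.90 ± 3.57 and 19.6 ± 2.56, and Slc25a53 at 1.20 ± 0.779 and 5.52 ± 2.28. The log2 difference between OE and KO was -0.16 (-1.33 to 1.00) for Sox9, 0.014 (-1.30 to 1.33) for Gfi1 (-0.012 in values as deposited) and 0.15 (-0.48 to 0.78) for Tcf7l2. Without KO 1 it was -0.22 for Tcf7l2, and without KO 2 0.52. For the gene Sox9 OE against KO gave -0.29 without KO 1, -0.038 without KO 2 and -0.0036 without the library labelled OE 1. For Gfi1 it was -0.16 without OE 4 and 0.30 without OE 2.

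Of the 34 lists, 13 passed camera at the preset correlation, 10 higher and 3 lower in OE, and 0 passed with an estimated correlation. Of 18 T cell genes, 17 were positive, with a median log2 difference of 1.04 (adjusted p = 1.46e-12, and adjusted p = 0.541 with an estimated correlation), and the median was 0.69 without KO 1. Beside Gzma and Lck, the chemokine Ccl5 was at 53.1 ± 32.4 in OE and 8.17 ± 4.74 in KO, and Cd3g at 21.2 ± 13.9 and 11.1 ± 4.96. All 15 genes of the list of dissociation and immediate early genes were positive, with a median log2 difference of 0.48 (adjusted p = 0.000205, and adjusted p = 0.541 with an estimated correlation). Hsph1 was at 42.8 ± 25.1 and 21.9 ± 12.6, Zfp36 at 33.4 ± 15.0 and 21.9 ± 2.71, Fos at 26.7 ± 12.9 and 12.8 ± 10.2, and Junb at 22.4 ± 7.11 and 15.6 ± 3.81. Of 17 tuft cell genes, 16 were positive, with a median log2 difference of 0.76 (adjusted p = 0.00377, and adjusted p = 0.786 with an estimated correlation), and the median was -0.18 without KO 2, when the list did not pass, and 1.52 without KO 1. Sh2d6 was at 47.6 ± 30.6 and 24.5 ± 22.7, Lrmp at 20.8 ± 10.5 and 10.9 ± 11.6, and Trpm5, a cation channel of tuft cells, at 16.2 ± 7.99 and 11.3 ± 12.4. Of 13 Paneth cell genes, 11 were positive, with a median log2 difference of 0.63 (adjusted p = 0.0132, and adjusted p = 0.786 with an estimated correlation). The adjusted p was 0.305 without KO 1, 0.0823 without OE 3 and 0.107 without OE 5, and the median was 1.29 without KO 2. Itln1 was at 1226 ± 729.7 and 712 ± 532, Ang4 at 525 ± 487 and 165 ± 59.0, Mptx2 at 266 ± 171 and 168 ± 113, and Lyz1 at 1556 ± 1257 and 1591 ± 1419.8. Of 25 genes of endoplasmic reticulum stress, 18 were positive, with a median log2 difference of 0.44 (adjusted p = 0.00465, and adjusted p = 0.786 with an estimated correlation), and the median was 0.17 without KO 1, when the list did not pass, and 0.30 without OE 4. Calr was at 409.8 ± 69.0 and 223 ± 7.31, Hsp90b1 at 346 ± 86.0 and 282 ± 25.1, Canx at 247 ± 33.7 and 349 ± 115, and Pdia3 at 255 ± 55.5 and 274 ± 144.

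Genes of the interferon response (median 0.43), B and plasma cells (0.60), the cell cycle (0.23), MHC class II (0.43) and alpha-defensins (0.83) also passed as higher in OE than in KO at the preset correlation, each with an adjusted p of 0.786 with an estimated correlation. Fibroblasts (median -0.63), macrophages and dendritic cells (-0.37) and sex-linked genes (-1.70) passed as lower, also each with an adjusted p of 0.786 with an estimated correlation. The means of the sex-linked genes, all Y-linked, were 0.073 in OE 3 and 0.040 in OE 4, 2.89 to 3.59 in the other OE libraries and 3.58 and 4.29 in KO (mean log2). Without Ctrl 3, OE 3 and OE 4, a choice made after seeing the data, the median of these genes was -0.79. When the library in brackets was left out, calls were lost for the interferon response at a median of 0.13 (KO 1), B and plasma cells at 0.19 (KO 2) and 0.25 (OE 4). Lost too were those for the cell cycle (proliferation) at -0.13 (KO 1) and 0.23 (OE 3), MHC class II (mhc2) at -0.0038 (KO 1) and 0.35 (labelled OE 1) and alpha-defensins at 0.46 (KO 1), 0.74 (OE 3) and 0.49 (OE 5). They were also lost for fibroblasts at -0.67 (Ctrl 2), 0.026 (KO 1), -0.55 (OE 2), -0.43 (OE 4) and -0.60 (OE 5) and for macrophages and dendritic cells at 0.21 (KO 1) and -0.29 (OE 2). Other medians that moved over 1.5-fold were 0.67 (OE 3) for the interferon response, 1.05 (KO 1) for B and plasma cells and 0.55 (KO 2) for the cell cycle. They were 0.75 (KO 2) for MHC class II, -1.45 (KO 2) and -1.09 (labelled OE 1) for fibroblasts and -0.73 (KO 2) and -0.59 (labelled OE 1) for macrophages and dendritic cells. Over all genes tested, 0 list members were called, and adjusted over the list alone there were 9. These were Gzma, Gzmb, Cd3e, Cd8a, Ccl5 and Lck of the T cell list, Stat5a and Stat5b of the JAK-STAT list, and Cxcl5, at 0.452 ± 0.559 in OE and 4.07 ± 0.0947 in KO, and those beyond the naming rule were named after their values were seen.

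In limma, 0 of 13056 genes were higher and 0 lower in OE than in KO, with 385 at an unadjusted p under 0.05 against 652.8 by chance, and robust limma and library weights also called 0. Without the library labelled OE 1, alone or together with Ctrl 2, a choice made after seeing the data, 1 gene was lower, the predicted gene Gm11794. Of the 13 lists, 5 kept their call and direction without KO 1, and 10 to 13 without any other library.

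Across the 13056 genes, which are not independent replicates, the log2 differences of KO and of OE against the shared Ctrl libraries had a Pearson r of 0.637 and a Spearman rho of 0.610. Unchanged groups and 3 shared controls, all simulated as independent noise with the same spread per gene in every group, gave 0.502 and 0.463. No simulated control stood apart as Ctrl 2 did, so the simulated values are no firm baseline for these data. The covariance was 0.214 against 0.152 simulated. Without Ctrl 2, r was 0.511 and the covariance 0.135, below the simulated 0.597 and 0.192. There were 0 genes called by limma in both comparisons, so no overlap of calls could be counted.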

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

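The tests of villus cells, of the intestinal segment and of the epithelial share, and the counts of splits that concern genes, were chosen after the results they measure were seen. Of 125 measures examined for a library far from the other 4 of the OE group, 2 stood out, where chance gives about 6.25. The mean log2 level of the mitochondrial respiratory chain was 14.4 in the library labelled OE 1 and 13.3 to 13.6 in the others, a gap of 0.771 of the whole range. The log2 level of Cd8a, a T cell coreceptor, was 1.87 in OE 2 and 3.33 to 3.87 in the others, a gap of 0.730 of the range. The critical value for 5 samples is 0.71.

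Ctrl 2 differed from all other libraries in mitochondrial share, number of genes and cell type markers. Mitochondrial RNA taking the room of other transcripts would leave their ranks alone. Over 1385 abundant genes outside the mitochondria, the median Spearman correlation of Ctrl 2 with the other libraries was 0.443, against 0.698 to 0.813 among the others. This test cannot decide, since the genes were chosen by a mean that includes Ctrl 2. Lct, for example, was at 541 scaled TPM in Ctrl 2 and at most 32.9 in any other library. Sampling noise, at an unknown depth, could also lower the correlation of Ctrl 2. More villus cells and fewer crypt cells in that preparation stay open: 4 of 4 list means (enterocyte highest, and Paneth, stem and cell cycle lowest) lay outside the range of the other libraries, but these lists are part of what set Ctrl 2 apart, and the enterocyte rank depends on the scaling, so they do not support it. A more proximal segment stays open too: in scaled values the mean of proximal small intestine genes was 6.21 in Ctrl 2 against 1.76 to 4.14 elsewhere, and that of ileal genes 4.21 against 4.30 to 5.34, which minus the mean of the others is -0.43, within 2 of their SD of 0.315. No other explanation was tested.

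Y-linked transcripts were near 0 in Ctrl 3, OE 3 and OE 4, except Uty in Ctrl 3. Low detection is argued against by 2520 autosomal genes with means of 20 to 100 scaled TPM, of which at most 0.913% were under 1 TPM in these libraries. Among the Y-linked genes this covers only Eif2s3y, at 25.2 to 89.7 scaled TPM in the other libraries. Ddx3y was at 8.97 to 14.5 and Kdm5d at 1.59 to 6.93 in those libraries, below the range tested. Female mice under a male label are a candidate explanation, tested by the X-linked genes Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which escape inactivation. Their mean log2 level was 5.53, 5.53 and 5.74 in these libraries and 4.41 to 5.38 in the others. The gap of 0.15 is small beside the spread of the others. In Ctrl 3, Uty was at 2.70 TPM and Eif2s3y at 0.756, with Ddx3y and Kdm5d at 0. As deposited, Uty was at 0.874 (Ctrl 2) to 16.8 TPM (KO 2) in the libraries not low in Y-linked transcripts. Its level in Ctrl 3 thus lies within their range and goes against a female mouse there, and its source was not tested. The 3 libraries fall in the Ctrl and OE groups and in neither KO library, so sex stays open as a contributor to comparisons with KO.

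T cell transcripts were higher in OE than in KO at the preset correlation, with adjusted p = 0.541 with an estimated correlation. More leukocytes in the OE preparations stay open: 11 of 11 tested leukocyte genes outside the fixed lists had higher means in OE, with a median log2 difference of 0.63 and an exact permutation p of 0.333, but 12 of 14 macrophage and dendritic cell genes had lower ones, with a median of -0.37 (adjusted p = 0.0153 in camera, and adjusted p = 0.786 with an estimated correlation), which goes the other way. Of the 11, Coro1a was at 56.8 ± 37.2 scaled TPM in OE and 22.6 ± 19.4 in KO, and Lcp1 at 18.9 ± 11.3 and 10.6 ± 2.19. A lower epithelial share would raise fibroblast genes too, whose mean difference was -0.63, but the difference between the T cell and fibroblast means had an exact permutation p of 0.143 over 21 splits, so this cannot be told apart from the first. The Stat5 manipulation itself also stays open, as untested.

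Other splits of the 8 Ctrl and OE libraries into 3 and 5 do not exclude chance for OE against Ctrl. The count of genes past the threshold in limma tells nothing here, since the real count of 0 is reached by 56 of 56 splits whatever the data, with up to 6 elsewhere. At an unadjusted p under 0.05, 17 of the 56 splits gave as many genes as the real 797, up to 1960. As many as the 14 lists past the threshold were given by 9 of the 56 splits, up to 20. The median over the splits other than the real one was 11 lists.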

How the results depend on the processing

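The settings with protein-coding genes only, with the Y-linked covariate, without Ctrl 3, OE 3 and OE 4, and without Ctrl 2 and the library labelled OE 1, and the exact test of list means, were chosen after seeing the data. Of 105 values of named genes, 72 had the same direction in every setting, 29 turned sign when 1 library was left out and 26 in another setting, and 1, Rps2-ps13, passed the threshold in any setting. Leaving out 1 KO library leaves the other, which is then assumed to vary like the other groups. TPM keep no read numbers, so what depth limits cannot be stated, and the median 95% half-widths of 0.94, 0.75 and 0.86 on the log2 scale are the precision of the 3 comparisons. In limma, robust fits, library weights, both pseudocounts, quantile normalization, values as deposited, the stricter filter, a false discovery rate of 0.1, a 1.5-fold minimum, protein-coding genes only and the Y-linked covariate gave 0 genes in each comparison, as against 452, 797 and 385 at an unadjusted p under 0.05. The count-based alternatives were not run, since the values are not counts.

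Without a filter, 5 genes were higher in KO than in Ctrl and 7 lower in OE than in KO, and with only the groups compared 1 gene was higher in KO than in Ctrl (Rps2-ps13) and 1 in OE than in Ctrl (Gm12252). Without Ctrl 3, OE 3 and OE 4, 1 gene, Gm13015, was higher in OE than in Ctrl and 1 in OE than in KO, and without Ctrl 2 and the library labelled OE 1, 1 gene was lower in OE than in KO and the correlation of KO and OE changes was 0.498. The number of gene lists past the threshold was 0 in each comparison by camera with an estimated correlation, by directional fry, by mixed fry and by the exact permutation test of the list mean. The exact permutation test says little: its smallest p before adjustment over 34 lists is 0.1 for KO against Ctrl, where 0 was fixed by the design, and 0.0476 for OE against KO, where almost every list would have to reach it. The number of lists past the threshold by camera at the preset correlation was 8 for OE against Ctrl with the stricter filter and 7 for OE against KO with the Y-linked covariate. Of the 14, 14 and 13 lists called for KO against Ctrl, OE against Ctrl and OE against KO, 9, 12 and 12 kept call and direction in values as deposited, 12, 10 and 12 with quantile normalization, 12, 8 and 10 with the stricter filter, and 11, 8 and 3 with the replicate block. Without Ctrl 3, OE 3 and OE 4, 10, 8 and 8 kept them, with the Y-linked covariate 12, 14 and 6, without Ctrl 2 and the library labelled OE 1 8, 10 and 12, and with both pseudocounts, no filter or protein-coding genes only 11 or more. Without Ctrl 2 and the library labelled OE 1, turned values for KO against Ctrl were alpha-defensin genes -0.35, cell cycle genes -0.12, Sox9 -0.12, Gfi1 -0.22, Defa30 -0.28, Defa24 -0.45, Defa31 -0.84, Defa17 -0.74, Fabp6 -0.63, Irf1 0.052, Ctss 0.23, Canx -0.48 and Pdia3 -0.10. Without Ctrl 2 and the library labelled OE 1, turned values for OE against Ctrl were Sox9 -0.13, Gfi1 -0.16 and Mcl1 0.028. Without Ctrl 2 and the library labelled OE 1, turned values for OE against KO were Pdia3 0.042. Without Ctrl 3, OE 3 and OE 4, turned values for KO against Ctrl were tuft cell genes 0.26. Without Ctrl 3, OE 3 and OE 4, turned values for OE against Ctrl were Tcf7l2 0.032, Cdkn1a 0.34 and Mcl1 0.15. Without Ctrl 3, OE 3 and OE 4, turned values for OE against KO were Gfi1 -0.28. In values as deposited, turned values for KO against Ctrl were Tcf7l2 0.21, Psmb8 0.15, Irf1 0.37, Ctss 0.45 and Hsp90b1 0.053. In values as deposited, turned values for OE against Ctrl were Tcf7l2 0.35, Cdkn1a 0.43, Socs2 0.16 and Mcl1 0.47. In values as deposited, turned values for OE against KO were Gfi1 -0.012. With library weights, turned values for KO against Ctrl were Gfi1 -0.11, Defa24 -0.37, Defa31 -0.58, Defa17 -0.36, Fabp6 -0.25, Psmb8 0.11, Irf1 0.12, Ctss 0.26 and Canx -0.34. With library weights, turned values for OE against Ctrl were Gfi1 -0.20, Lyz1 -0.18, Cdkn1a 0.23 and Mcl1 0.16. With library weights, turned values for OE against KO were Gfi1 -0.10. With quantile normalization, turned values for KO against Ctrl were Ctss 0.019. With quantile normalization, turned values for OE against Ctrl were Mcl1 0.040. With quantile normalization, turned values for OE against KO were Gfi1 -0.046. With a pseudocount of 0.1, turned values for OE against KO were Gfi1 -0.11. With the Y-linked covariate, turned values for OE against KO were Gfi1 -0.32. The cause was not tested.

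When 1 library was left out, 0 to 2 genes were lower in KO than in Ctrl, 0 to 1 higher in OE than in Ctrl, 0 to 2 higher and 0 to 1 lower in OE than in KO. Those in comparisons with KO were Gm6863 and ENSMUSG00000044341 without KO 1, Gm6654 without OE 3 and Gm11794 without the library labelled OE 1, and in OE against Ctrl Gm12252 without KO 1 or KO 2. The lists past the threshold numbered 4 to 17, 9 to 18 and 5 to 15 for KO against Ctrl, OE against Ctrl and OE against KO. The correlation of KO and OE changes was 0.470 to 0.780. Unchanged groups were simulated only with all libraries and without Ctrl 2. Neither this range nor the value without Ctrl 2 and the library labelled OE 1 thus has a simulated value beside it. The lowest and highest log2 differences of genes, and medians of lists, were as follows. For KO against Ctrl they were alpha-defensin genes -0.35 to 1.86, cell cycle genes -0.12 to 0.82, tuft cell genes -1.17 to 0.37, Tcf7l2 -0.63 to 0.11, Sox9 -0.12 to 1.02, Gfi1 -0.22 to 0.71, Defa30 -0.28 to 4.89, Defa24 -0.45 to 1.56, Defa31 -0.84 to 1.16, Defa17 -0.74 to 1.69, Fabp6 -0.63 to 1.43, Tap2 -1.44 to 0.37, Psmb8 -0.82 to 0.11, Irf1 -0.35 to 0.053, Ctss -0.48 to 0.33, Col1a1 -0.47 to 1.81, Canx -0.48 to 0.40 and Pdia3 -0.50 to 0.62. For OE against Ctrl they were enterocyte genes -1.34 to 0.11, respiratory chain (list oxphos_mito) genes -1.23 to 0.14, Sox9 -0.29 to 0.85, Gfi1 -0.21 to 0.72, Cdkn1a -0.35 to 0.18, Socs2 -0.75 to 0.078 and Mcl1 -0.18 to 0.066. For OE against KO they were cell cycle genes -0.13 to 0.55, tuft cell genes -0.18 to 1.52, macrophage genes -0.73 to 0.21, fibroblast genes -1.45 to 0.026, Tcf7l2 -0.22 to 0.52, Gfi1 -0.16 to 0.30, Itln1 -0.024 to 1.67, Mptx2 -0.11 to 1.37, Lyz1 -1.08 to 1.05, Lrmp -0.032 to 2.42, Sh2d6 -0.022 to 2.12, Trpm5 -0.43 to 2.14 and Pdia3 -0.58 to 0.54. The cause was not tested.

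Whether the replicate numbers pair the samples cannot be told. Of 7 pairs with the same number, 0 had deviations correlated above 0.1 (-0.18 to 0.063). Pairs with different numbers ranged from -0.216 to 0.227, and the deviations of the 2 KO libraries mirror each other, so these values cannot decide. With the replicate number as a block, 2 genes were higher and 1 lower in OE than in Ctrl (Atp6v0c, Gm6311 and Rps2-ps10), and 9 lists passed for OE against Ctrl and 4 for OE against KO. With the block, turned values for OE against KO were Paneth cell genes -0.016, tuft cell genes -0.00019, Gfi1 -0.68, Ang4 -0.54, Mptx2 -0.48 and Lyz1 0.12.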

Other observations

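Red blood cell genes had a mean log2 level of 2.18 ± 0.283 in Ctrl (SD, n = 3), 2.86 ± 0.468 in KO (SD, n = 2) and 3.66 ± 1.09 in OE (SD, n = 5), and mast cell genes were at 1.20 ± 0.686, 1.40 ± 0.363 and 2.01 ± 0.880. Goblet cell genes were at 5.59 ± 1.05, 5.62 ± 0.113 and 6.03 ± 0.556, and Lgr5 stem cell genes at 3.16 ± 0.776, 3.48 ± 0.0140 and 3.41 ± 0.411. Genes of the Wnt list were at 3.27 ± 0.550, 3.60 ± 0.0279 and 3.54 ± 0.263. In Ctrl 1, 2 and 3 the means were 1.33, 0.465 and 1.82 for mast cell, 5.52, 4.57 and 6.67 for goblet and 3.57, 2.27 and 3.65 for stem cell genes. Ctrl 2 alone puts Ctrl below KO for these lists, and below OE for goblet and stem cell genes. Wnt genes were at 3.57, 2.63 and 3.60, so most of their gap to KO and OE rests on Ctrl 2 too. Goblet, stem and Wnt genes did not pass the list threshold in any of the 3 comparisons.

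Pseudogenes made up 652 of the genes tested and took between 13.5% and 24.6% of the TPM outside the mitochondria. Rps2-ps13 and Rpl30-ps9, among the genes with the smallest p, are of this class. The predicted gene Gm10222 had the value of the mitochondrial gene mt-Nd4l in all 10 libraries.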
